A study of Caenorhabditis elegans with 2 samples.

How the data were processed

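The series holds ChIP-seq of 2 biological replicates of young adult hermaphrodite worms that express NFYA-1 with a C-terminal tag, 1 technical replicate each, from chromatin broken by sonication. Grouping and replicate numbers were taken from the labels. Per the labels, an antibody against the fluorescent protein was used and the reads were placed on builds ce10 and ce11. The aligner, the peak caller and their versions are not given in the sources used here. Per the deposited descriptions of the files, there was for each build a peak list for replicate 1, for replicate 2 and for both pooled, each made from the alignments and a control file, which was the same for both replicates, and a final list that the authors thresholded with the irreproducible discovery rate. Peaks were thus called per replicate and on the pooled samples.

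Each deposited peak has a signal value, in the column meant for the strength of a peak, whose scale is not given in the sources used here. It was used only to rank and describe peaks within a list, so levels of different lists are given side by side and not tested. The deposited lists also carry a score in the column meant for q-values. The scale of this score is not given either, and it was negative at strong nuclear peaks. What the negative values mean was not tested, and the score was not used in any result. Every list before thresholding had 30000 peaks, a fixed length that includes background, so its length says nothing of the number of sites. No read counts or library sizes were used, the depth is unknown, and the precision of a signal value cannot be given; intervals cover the counting of regions only.

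All positions are on ce11, whose sequence and annotation are the WBcel235 genome and Ensembl release 115. Builds were never converted. Coordinates of ce10 were used only among the ce10 lists themselves, to merge and overlap peaks, and no ce10 position was set against genes or sequence. The circular shifts of ce10 lists used the chromosome lengths of ce11. Mitochondrial genes were named by their overlap with the RefSeq annotation of the same assembly. Peaks overlapping by 1 bp or more were merged, keeping the summit of the strongest. The background was the merged pooled peaks that overlap no final region, 29407 in number, all nuclear. A summit was called at a gene start from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start. CCAAT was sought on both strands within 50 bp of the summit, and words of 6 bases in the same 101 bp. Matched backgrounds had 10 peaks per region within 2 percentage points of GC.

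Shares were compared with two-sided Fisher's exact tests, with exact conditional 95% intervals of odds ratios and exact Clopper-Pearson intervals of shares. An approximate interval of odds ratios was used at first and was replaced after results were seen, because at a count of 1 it excluded 1 where the exact p did not reach 0.05. The change left 2 explanations in the closing part undecided, those on abundant genes and on CCAAT in the mitochondrion. Medians and rank correlations were tested with 100000 permutations and overlap of the replicates with 1000 circular shifts along each chromosome. Families of tests were adjusted by the Benjamini-Hochberg method at 0.05, over 2080 words, 21 gene lists, 8 noncoding classes or the chromosomes. Both replicates are separate biological samples per the labels, but with 2 samples of 1 group no test across samples was possible, and p-values refer to regions or genes within these lists. Copies of regions were sought with BLAST 2.17.0 at 90% identity over 100 bp. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

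The tests were also run on sets with known answers, drawn from the real weaker peaks or genes. The nuclear set size of 71 and the coding exon test were chosen after the data were seen. Random sets of 71 background peaks were called for CCAAT in 2% of 100 draws and for coding exons in 3%. The word ACCAAT, planted in 20% of windows, was found by the 6-base search in 100% of 20 draws. Every planted window received this same word. The rate therefore does not cover CCAAT with differing neighbouring bases, which the search divides among 8 words.

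Tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the genes nearest to the 20 strongest final regions, the genes nfya-1, nfya-2, nfyb-1, nfyc-1, egl-5, tbx-2 and unc-119, up to 4 bound members of each gene list, the 5 enriched words with the lowest p, and divergent gene pairs that share a region among the 20, of which there were none, since all mitochondrial genes are on the same strand. Because those 20 were all mitochondrial, the nuclear regions were ranked by the same rule afterwards. Nuclear-only settings, matched nuclear backgrounds, mitochondrial-only correlation, coding exon shares and GC content were also added afterwards, as were the distances used for neighbouring regions, windows alike in coding content, single replicates in the nucleus, the odds ratios of enriched words in single replicates and the exact binomial test of noncoding genes against mitochondrial positions. Alternatives covered the window sizes, the backgrounds, merging, overlap rules, the number of regions, the build and each replicate's list alone.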

Results

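The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for NFYA-1, the worm form of the A subunit of NF-Y, a transcription factor complex known for binding the sequence CCAAT. The samples are whole young adult hermaphrodites of Caenorhabditis elegans strain OP404. This strain carries an integrated transgene that expresses NFYA-1 fused at its C-terminal end to a green fluorescent protein and FLAG tag, and the tagged protein was pulled down with an antibody against the fluorescent protein. The samples form 1 group of 2 biological replicates, so the comparisons possible are between the replicates, between the final peaks and weaker peaks of the same list, and between 2 builds of the genome. Each replicate list and the list from both replicates pooled held 30000 peaks on each build. The read depth is unknown, because the lists carry no read counts. All positions are on build ce11, the assembly also named WBcel235, and signal values are those the authors deposited for each peak.

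The strongest regions lay in the mitochondrial genome. The region with the highest signal value, 2947, covered M 9894 to 10413 with its summit in COX2, a subunit gene of cytochrome c oxidase. The next, at 2294, covered M 7023 to 7465 with its summit in ND4, a subunit gene of the respiratory NADH dehydrogenase, and the region at M 5018 to 5429 in CYTB, which encodes cytochrome b, had 1659. In the nucleus the highest values were 83.4 at pot-3, a homologue of the telomere-binding protein POT1, and 80.8 in an untranslated exon of Y69H2.9. The final list, made by the authors with the irreproducible discovery rate and called the optimal list, held 97 peaks. They merged into 92 regions, of which 71 were nuclear and 21 mitochondrial, with median peak signal values of 40.1 and 941.

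By transcript start, the 20 regions with the highest signal were all assigned to mitochondrial genes. The genes nearest to these summits were COX1, COX2, COX3, CYTB, ATP6, ND1, ND2, ND3, ND4, ND4L, ND5 and ND6, which are all 12 protein-coding genes of that genome, encoding parts of the respiratory chain and ATP synthase. Summits lay within the coding sequence of COX2, ND4, CYTB, ND5, COX1, ATP6, COX3, ND6, ND1, ND3 and ND2, in both ribosomal RNA genes, and in the tRNA genes for glutamine, leucine and asparagine. Signal values in this set ran from 2947 down to 96.1 at ND2, M 3708 to 3997. Together the 21 mitochondrial regions covered 6580 bp, or 47.7% of the mitochondrial genome of 13794 bp. Mitochondrial peaks made up 26 of the 97 final peaks, 26.8%, but only 0.0867% of the 30000 peaks in the pooled list.

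**Figure D1:**
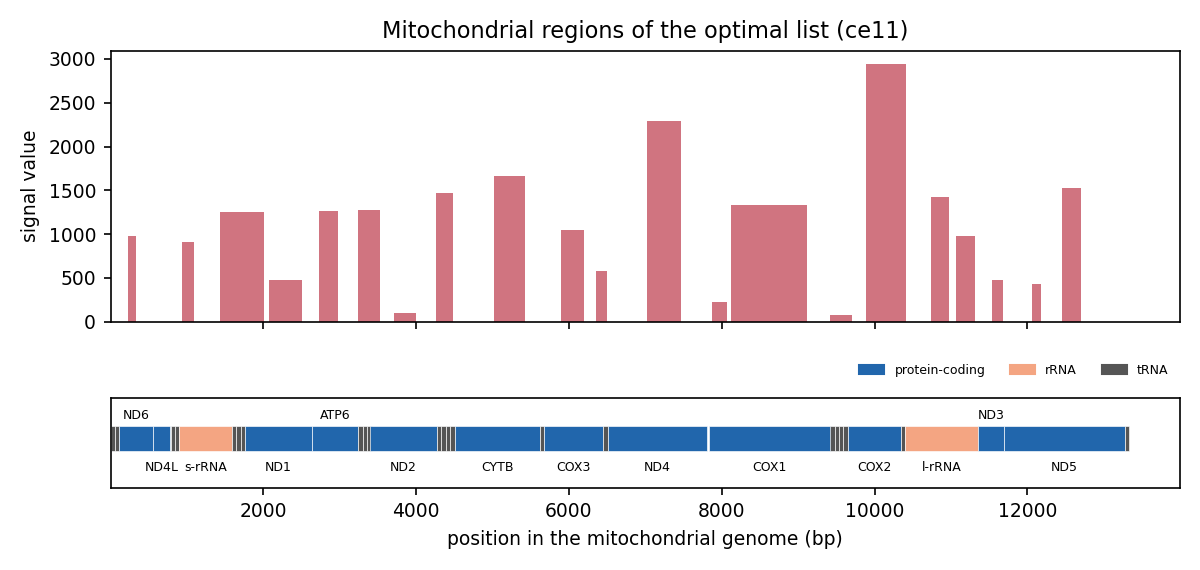
Signal value of the 21 mitochondrial regions of the final list (upper panel, bar width is the merged region) by position in bp, above the annotated genes (lower panel). Regions are spread over the protein-coding and ribosomal RNA genes, and the highest, at 2947, lies in COX2.

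Among nuclear genes, pot-3 held the strongest region, at III 13780163 to 13780452, in a coding exon with the summit 93 bp downstream of the transcript start. This region lies near the end of chromosome III, which is 13783801 bp long. On chromosome V, 3 regions stood within 5871 bp of each other, at Y69H2.9 (18705520 to 18705809, signal 80.8), in an intron of Y17D7C.1 (18708086 to 18708375, signal 49.6) and in a coding exon of Y17D7C.6 (18711391 to 18711680, signal 41.7). Coding exons of Y50D4C.5 (V 1001579 to 1001868, 55.4), F53F4.11 (V 13624079 to 13624368, 52.1), Y41E3.1 (IV 14955753 to 14956042, 49.6) and nmy-1, a non-muscle myosin heavy chain gene (X 2914884 to 2915173, 47.7), were also among the strongest. Further coding exon summits among the 20 strongest nuclear regions were in pqn-72 (46.0), the cap-binding translation factor gene ife-5 (45.2), nsph-3.1 (45.1), Y69A2AR.18 (44.4), W05F2.4 (44.4), the cathepsin B-like protease gene cpr-5 (43.4), the aldehyde dehydrogenase gene alh-9 (43.1), best-22 (42.5) and let-711, which encodes the scaffold of the CCR4-NOT deadenylase (42.3). The summit at 44.1 lay in a coding exon of the cuticle collagen gene col-123, which sits inside the larger gene catp-6. The region nearest to taf-5, a subunit gene of the general factor TFIID, had its summit in a coding exon of the neighbour F30F8.5, at I 7848265 to 7848554, and an intron of tig-3 held another. The region nearest to T28H10.2, V 12509944 to 12510233 at 47.7, was intergenic. BLAST gave 215 alignments of it to the genome, its own place included, and overlapping alignments were not merged. By contrast, 70 of the 71 nuclear regions matched the genome only at their own place. These 20 nuclear regions were picked by the rule fixed for the whole list, applied to the nucleus after the data were seen, while the region in Y17D7C.6, and that in vps-34 described with CCAAT, ranked 24 and 23 in the nucleus and were chosen after their values were seen.

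The replicates shared more of their strongest regions than shifted positions did. Of the 92 highest-ranked regions of replicate 1, 24 (26.1%) were overlapped by the 92 highest of replicate 2, against a mean of 17.6% and a maximum of 21.7% after 1000 circular shifts (one-sided permutation p = 0.001, the smallest that these shifts can give). Within the nucleus the overlap was 6 of 71 regions, 8.45%, against 0.0521% after shifts, and it was 102 of the 1000 highest nuclear regions, 10.2% against 0.635% (one-sided permutation p = 0.001 each, also the smallest). The region at pot-3 ranked 21 in replicate 1 and 24 in replicate 2, and that at Y69H2.9 ranked 23 in both. F53F4.11 and pqn-72 were unequal, with ranks of 2023 and 2059 in replicate 1 but 25 and 43 in replicate 2, and best-22 ranked 10753 and 39. All 71 nuclear regions were overlapped by a peak in each replicate list, with a median nuclear rank of 708 in replicate 1 and 71 in replicate 2. The lists of both replicates were made against the same control file, which is not analysed here.

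Signal values of COX2 were 836 in replicate 1 and 2139 in replicate 2, those of ND4 at M 7023 to 7465 were 794 and 1530, and those of pot-3 were 45.4 and 44.5. Across the 90 final regions found in both replicate lists, the signal values of the replicates correlated with Spearman rho = 0.294 (two-sided permutation p = 0.00528). The 19 mitochondrial regions gave rho = 0.816 (permutation p = 9e-05) and the 71 nuclear regions gave rho = -0.434 (permutation p = 0.00016). Regions are not independent replicates, and these had been selected on the signal of both samples together. The median nuclear peak signal, 40.1, was close to the lowest kept, 38.6. A cut on the pooled signal so near the values favours a negative rho by itself. The nuclear rho and its p-value therefore do not measure how well the replicates agree.

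**Figure D2:**
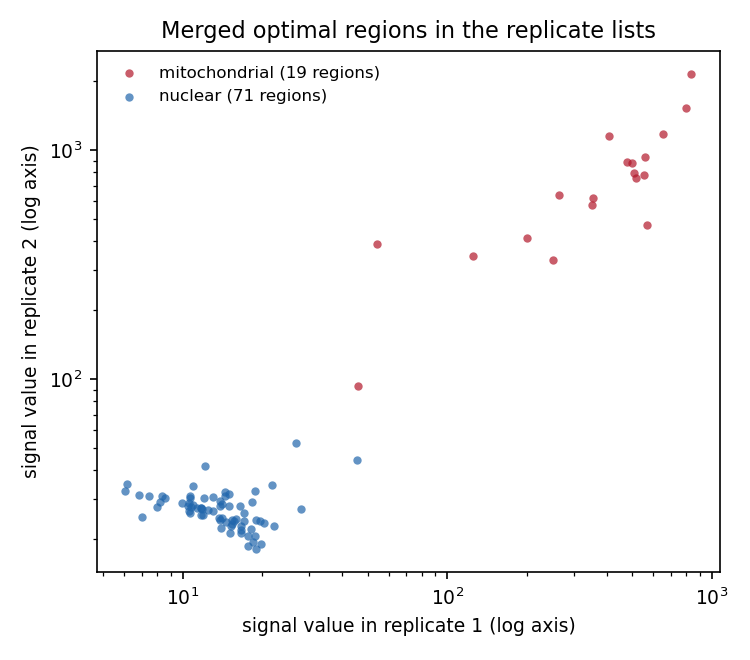
Signal value in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, for the 90 final regions found in both lists, 1 point per region. The 19 mitochondrial regions rise together (rho = 0.816) and lie mostly apart from the 71 nuclear regions, whose values run in opposite directions (rho = -0.434). Selection of the final regions on the pooled signal favours the negative sign in the nucleus.

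Nuclear summits lay mainly in coding exons. Of 71 nuclear summits, 59 (83.1%, exact 95% interval 72.3 to 91.0) were in a coding exon, 7 in an intron, 1 in an untranslated exon, 2 upstream of a gene and 2 in intergenic sequence. Besides the genes above, coding exon summits were in dhc-1 (signal 38.7), the heavy chain of cytoplasmic dynein, dys-1 (39.9), the worm dystrophin, inx-2 (38.8), an innexin, and hmr-1 (38.8), the worm cadherin. These 4 were chosen after their values were seen. Weaker pooled peaks that overlapped no final region were in coding exons in 46.6% of 29407 cases, giving an odds ratio of 5.63 (95% interval 2.99 to 11.5, two-sided Fisher's exact p = 4.03e-10). It was 3.10 against the 5000 strongest weaker peaks, and 4.27 and 2.92 for the strongest nuclear regions of replicate 2 and of replicate 1 alone. Along the nuclear pooled list the coding share fell from 83.1% in ranks 1 to 71 to 71.7% in ranks 201 to 500 and 39.1% in ranks 20001 to 29478. The summit windows of the 71 regions had a median GC content 7.92 percentage points above that of the weaker peaks (permutation p = 1e-05, the smallest 100000 permutations can give). The difference was 4.95 points against the 5000 strongest weaker peaks and also for replicate 1 alone. Against weaker peaks matched on GC content, 59.9% of which were in coding exons, the odds ratio was 3.30 (1.71 to 6.85, exact p = 9.41e-05). Both measures were added after the data were seen.

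**Figure D3:**
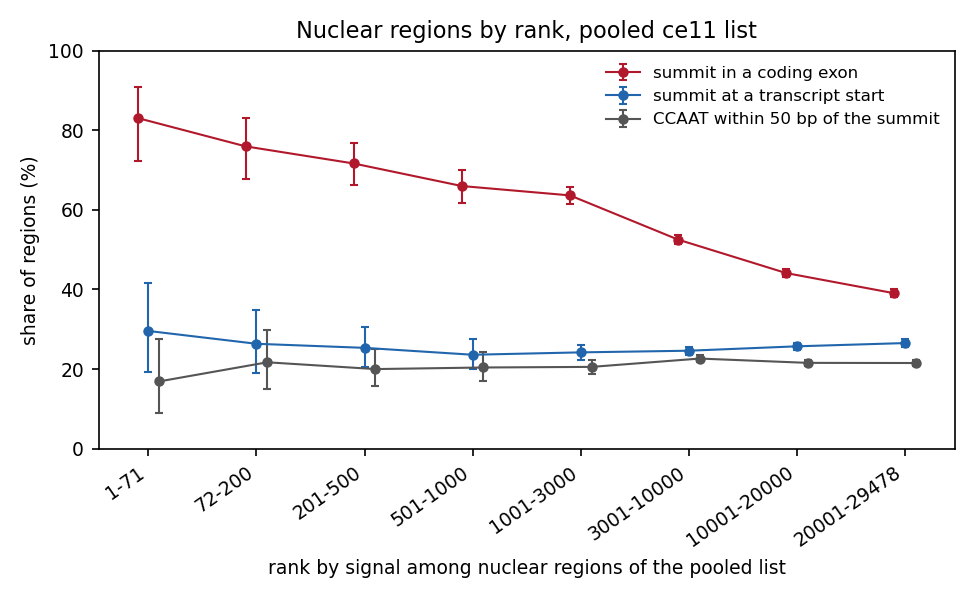
Share of nuclear regions (y axis, percent) with the summit in a coding exon, at a transcript start, or with CCAAT within 50 bp, by rank of signal in the pooled list (x axis). Points are shares and bars exact 95% intervals. The coding share falls from 83.1% to 39.1%, while CCAAT is at 16.9% in the highest and 21.5% in the lowest ranks.

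Whether NFYA-1 regions lay at gene starts was asked with a window from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start. The nuclear regions at a start included those of pot-3, ife-5, let-711, taf-5, cpr-8 and dnj-27, and a region in Y69A2AR.18 was also in the window of ccdc-12. Nuclear summits were at a start in 21 of 71 cases, 29.6% (exact interval 19.3 to 41.6), with an odds ratio of 1.22 against weaker peaks (0.697 to 2.07, Fisher's exact p = 0.417). With the mitochondrial regions included, the odds ratio was 2.14 (1.38 to 3.30, exact p = 0.000457), but 77.1% of the mitochondrial genome lies in such windows and the weaker peaks include none there. Against random positions on the same chromosomes the odds ratio was 1.18 (exact p = 0.453).

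The gene groups fixed before the data were examined were mostly without a bound member. Of 34 genes with a final region in the start window, among 19985 protein-coding genes, 22 were nuclear and 12 mitochondrial. The 34 were 0.170% of all genes, so lists of the sizes used here were each likely to hold none. Bound list members were ife-5, a form of the cap-binding protein eIF4E, with the summit at II 12283497 in a coding exon 139 bp downstream of the start (signal 45.2), and dnj-27, a chaperone of the endoplasmic reticulum, at I 11885138, 106 bp downstream (41.0). They were 1 of 39 translation factor genes and 1 of 20 genes of endoplasmic reticulum stress, each with adjusted p = 0.675 (Fisher's exact test, Benjamini-Hochberg over 21 lists). With all 34 bound genes, the unadjusted exact p was 0.0643 for the first and 0.0335 for the second, which alone was under 0.05. With the 22 nuclear bound genes only, both were under 0.05, at 0.0421 and 0.0218, and neither passed (adjusted exact p = 0.442 for both). Neither ife-5 nor dnj-27 was bound in the 92 strongest regions of either replicate alone, and those of replicate 1 held 1 proteasome gene instead. No member was bound among 49 cell cycle genes, 72 histone genes, 79 ribosomal protein genes, 33 proteasome genes, 27 heat shock and chaperonin genes, 24 lipid synthesis genes, 6 vitellogenins or 176 collagens. The same held for 28 Hox and patterning genes, 21 tubulin and actin genes, 39 nuclear respiratory chain genes, 19 oxidative stress genes and the 6 NF-Y subunits and reported targets. Markers of the germline (41 genes), neurons (30), muscle (21), intestine (18), hypodermis (20) and pharynx (16) also had 0 bound members. In simulations of 34 bound genes, the test called the 79 ribosomal protein genes in 0% of draws with 2 bound members and in 100% with 3. It called the 176 collagens in 2% of draws with 3, so a few bound members in a long list were not detectable.

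The genes of the complex itself and its reported targets had no final region at their starts. Only 0.170% of all protein-coding genes had one, so this was likely in advance and does not show a lack of binding. The final region nearest to a transcript start of nfya-1 was 432877 bp away, that of nfyb-1 84146 bp and that of nfyc-1 507405 bp, and the corresponding distances were 109770 bp for nfya-2, 859550 bp for the Hox gene egl-5, 721571 bp for the T-box gene tbx-2 and 34343 bp for unc-119. Weaker peaks of the pooled list fell in the start windows of nfyc-1 (best rank 1075, signal 28.8), unc-119 (rank 4574) and nfyb-1 (rank 9103, 19.9), and none in those of nfya-1, nfya-2, egl-5 or tbx-2. The transgene brings an extra copy of nfya-1 and, in strains of this kind, an unc-119 rescue gene, so both loci were examined for excess peaks. Within 20 kb of nfya-1 (X 11944285 to 11946838) and of unc-119 (III 10902641 to 10908935) there were 0 final regions. Of random windows, 98.65% and 97.89% held 0 as well, so this count says little. The pooled list held 3 peaks in the nfya-1 window against a mean of 11.8 in 10000 random windows of the chromosome, and 9.09% of these held as few. The unc-119 window held 23 against 11.9, with as many in 9.03% of random windows, and 1 of the 23 was in unc-119 itself. Among windows alike in coding content the mean was 10.6 and 4.29% held as many, while for the lists of replicates 1 and 2 the shares were 2.61% and 5.89%.

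CCAAT, the sequence known for NF-Y, was no more frequent in the final regions than in weaker peaks. At pot-3 a CCAAT lay 4 bp from the summit, at pqn-72 it lay at the summit, and in the vps-34 exon at I 6032343 to 6032632 it lay 13 bp away. The regions at Y69H2.9, Y50D4C.5 and F53F4.11 had no CCAAT within 250 bp. In all, 15 of 92 regions, 16.3% (exact interval 9.42 to 25.5), had CCAAT on either strand within 50 bp, against 21.7% of weaker peaks, an odds ratio of 0.703 (0.375 to 1.23, two-sided Fisher's exact p = 0.254). The nuclear share was 12 of 71, 16.9%, against 23.9% in weaker peaks matched on GC content and coding sequence, an odds ratio of 0.646 (0.309 to 1.25, exact p = 0.238). Ranked by odds ratio among the 30 words made of the same letters, CCAAT was number 25 for all regions. CCAAT was also planted in 71 windows drawn from weaker peaks, and only in windows that lacked it. The test found it in 99% of draws when 20% of the 71 were planted, and in 46% at 10%. Sites placed without regard to a CCAAT already present would raise the share less, so these rates overstate the power for them. Where a CCAAT lay within 250 bp, its median distance from the summit exceeded that in weaker peaks by 2 bp (60 regions, permutation p = 0.905). Among the strongest regions of replicate 2 alone the excess was 32 bp (permutation p = 0.0292), away from the summit.

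A search of all 2080 words of 6 bases found CGTGTC in 12 of 92 regions (13.0% against 2.92%, odds ratio 4.99, adjusted exact p = 0.0174) and AGGACA in 12 (13.0% against 3.20%, odds ratio 4.54, adjusted exact p = 0.0240). These were the only enriched words by Fisher's exact test with Benjamini-Hochberg adjustment, beside 2 depleted ones, and 150 words had an unadjusted p under 0.05. None of the 8 words that contain CCAAT was enriched, and 1 of them was more frequent than in weaker peaks. With a background matched on GC content 0 words were enriched, and 84 had an unadjusted p under 0.05. Against a GC-matched background of 710 peaks, odds ratios in the nucleus stayed above 1. They were 4.31 for AGGACA (unadjusted exact p = 0.000759) and 3.41 for CGTGTC (0.00136). Neither passed (adjusted exact p = 0.708 for both). Against all weaker peaks the nuclear odds ratios were 4.96 for AGGACA and 6.77 for CGTGTC. Matching also made the background much smaller, which lowers power, so the lost calls cannot be put down to GC content alone. In the strongest regions of either replicate alone, 0 words were enriched as well. There the odds ratios of replicates 1 and 2 were 2.30 and 2.72 for CGTGTC, and 1.73 and 4.11 for AGGACA.

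Summits near tRNA or ribosomal RNA genes were all mitochondrial, and no more frequent there than the layout of that genome gives. Of the 21 mitochondrial summits, 13 (61.9%) were within 500 bp of a tRNA gene and 6 (28.6%) within 500 bp of a ribosomal RNA gene. Of all mitochondrial positions, 68.2% and 26.4% are that close (exact binomial p = 0.640 and 0.807). Both classes passed Fisher's exact test over all 92 regions, but the weaker peaks there include no mitochondrial ones, so that outcome carries no information. Among the 71 nuclear regions, 0 were near tRNA or ribosomal RNA genes, which allows a share of up to 5.06%, and 0 of the 8 classes, including snoRNA, snRNA, miRNA, piRNA, other ncRNA and pseudogenes, passed the test or had an unadjusted exact p under 0.05. By chromosome, the mitochondrial genome held 21 of 92 regions against 0 weaker peaks, and X held 5 of 92 regions (5.43% against 16.7% of weaker peaks, odds ratio 0.286, adjusted exact p = 0.00651), among them nmy-1 and inx-2. The 21 mitochondrial regions lower the share of every nuclear chromosome among the 92, but not among the weaker peaks. Against counts of protein-coding genes X did not pass (odds ratio 0.363, adjusted exact p = 0.0623). Against chromosome lengths it did (odds ratio 0.268, adjusted exact p = 0.00313), with the mitochondrial regions again among the 92. In the nucleus alone, chromosome I held 21 of 71 regions (29.6% against 14.5%, odds ratio 2.48, adjusted exact p = 0.00629) and X held 7.04% (odds ratio 0.377, adjusted exact p = 0.0759). The X value was 4 of 92 in the strongest regions of replicate 2 (adjusted exact p = 0.00217) and 10 of 92 in those of replicate 1 (adjusted exact p = 0.281). Among the 71 strongest nuclear regions of a single replicate, chromosome I held 16 in replicate 2 (adjusted exact p = 0.189) and 12 in replicate 1 (adjusted exact p = 0.635). There X did not pass in replicate 2 (adjusted exact p = 0.0593) or in replicate 1 (adjusted exact p = 0.635).

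On the older build, ce10, the same strong signals were listed but fewer peaks were kept. The highest signal value was 2947 on both builds and the highest nuclear value 83.4 on both. The final ce10 list held 66 peaks in 61 regions, 40 nuclear and 21 mitochondrial, against 92 on ce11, and its X chromosome peaks numbered 1 against 5. On each build the final peaks were exactly the highest by signal in the pooled list, 66 of 66 and 97 of 97. The lowest signal value kept was 39.9 on ce10 and 38.6 on ce11, while the pooled lists had the same value, 39.9, at rank 66, so the lists differed in where the authors' threshold fell.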

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

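Nuclear-only and mitochondrial-only settings, GC-matched nuclear backgrounds and the coding exon and GC results were chosen after the data were seen; the other settings were planned. Of 92 alternatives, 68 were counted as unchanged. For results that are counts, such as lists or words called, this meant an equal or similar count. For the others it meant the same direction and side of the threshold. Unchanged were all 12 of the CCAAT share, all 7 of the replicate overlap, 5 of the coding exon share and 6 of GC content. So were all 8 of the gene lists, where no list passed in any setting. The count of 92 regions was 61 on ce10 and 46 by construction when only the stronger regions were kept. The rank correlation of the replicates was -0.434 in the nucleus, the opposite sign, where selection on the pooled signal is built in. The odds ratio at gene starts lost its call at 1.22 in the nucleus, 1.17 there with a GC-matched background and 1.18 against random positions, since the weaker peaks hold no mitochondrial ones. The distance of CCAAT, 2 bp, was -4 bp in the nucleus (permutation p = 0.826) and 19 to 32 bp with a single replicate; the cause was not tested. Enriched words fell from 2 to 0 with the 5000 strongest weaker peaks, the stronger 46 regions, windows of 100 bp, GC matching over all regions, or a single replicate (0 to 0). They rose to 9 in the nucleus, and there fell to 0 with GC matching and with GC and coding matching. Matched backgrounds also held far fewer peaks, which lowers power. Noncoding classes called were 0 in the nucleus instead of 2, which were all mitochondrial. Chromosomes called were 1 against gene counts, 1 in the nucleus, 1 to 2 with a single replicate and 0 with a single replicate in the nucleus. At 50 kb, 1 final region lay near a transgene locus. The odds ratio of coding exons was 2.92 to 4.27 with a single replicate. Unknown depth limits what weaker peaks can show. No paired analysis was possible because the series has 1 group.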

Other observations

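All tests here were chosen after the data were seen, and for every explanation but the draws matched for the replicates the deciding values had been seen as well. Several nuclear regions stood close together. Within 10 kb of another region were 9 of the 71, against a mean of 1.74 and a maximum of 9 in 1000 draws of weaker peaks matched on GC content and coding sequence (one-sided permutation p = 0.002). Of 5 distances tried, the excess held at 2, 10, 20 and 50 kb but not at 100 kb, where 16 regions had a neighbour against a mean of 10.6 (permutation p = 0.145). At 10 kb, besides the 3 regions at Y69H2.9, Y17D7C.1 and Y17D7C.6 on chromosome V, the pairs were in single genes. W05F2.4 on chromosome I had summits at 3377790 and 3378949, let-711 on III at 6952256 and 6954824, and Y69A2AR.18 on IV at 2495921 and 2496609, all in coding exons.

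Counting genes by a summit anywhere in the transcript, instead of at the start, added 3 list members to ife-5 and dnj-27. These were col-123, a cuticle collagen (signal 44.1), rpn-7, a subunit of the proteasome lid (39.9), and mat-2, a subunit of the anaphase-promoting complex (39.2), each in a coding exon. Of the 21 lists, 0 passed the test (lowest adjusted p = 0.798, Fisher's exact test), and 0 had an unadjusted p under 0.05. The lowest was 0.065, for the endoplasmic reticulum genes.

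The nuclear regions lay in coding exons in 83.1% of cases, with the share falling steadily down the ranks. GC content within 50 bp of the summit cannot be the whole cause, since the odds ratio against peaks matched on it was 3.30 (1.71 to 6.85), though matching lowered it from 5.63. GC content of the sequenced fragments was not tested. Binding directed by CCAAT is argued against by an odds ratio of 0.646 (0.309 to 1.25) in matched peaks, whose upper limit lies below a doubling. Abundant transcription of the genes may contribute and could not be ruled in or out, because only 1 of 59 coding exon summits lay in the 124 ribosomal protein, translation factor and vitellogenin genes, an odds ratio of 5.48 with an interval of 0.133 to 33.4. The regions may also hold NFYA-1 brought by partners, which was not tested.

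The mitochondrial regions spread over 47.7% of that genome, which leaves room for a part played by the high copy number of mitochondrial DNA. Of the 21 regions, 19 were overlapped by a peak in replicate 1 and 21 in replicate 2. That overlap cannot decide, because the regions were called on both replicates pooled and all 71 nuclear regions were overlapped too. The pooled list covered no more than the same 47.7%, and the signal of the peaks ran from 75.9 to 2947. Coverage by separate peaks does not measure how even the reads were. Copy number could thus be neither ruled in nor out, and the cause of the uneven peak signal stays open. CCAAT was in 3 of the 21 summit windows (14.3%) and in 23 of 94 other mitochondrial windows (24.5%), an odds ratio of 0.514 with an interval of 0.0896 to 2.02, so a moderate role of CCAAT there cannot be told apart from none with so few regions. Whether the control showed the same profile was not analysed here.

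The nuclear overlap of the replicates, 6 of 71 regions, might come from a shared preference for GC-rich exons. Draws from the replicate 2 list matched on both shared 0.287% on average and 2 regions at most, and 0% of 1000 draws reached 6, which argues against that preference as the whole cause. The control file shared by both replicates, local differences in copy number and true binding sites remain open and were not tested.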
